A study of Mus musculus with 10 samples.

How the data were processed

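RNA was sequenced from the left ventricle of ICR mice, an outbred laboratory stock, 4 weeks after an experimental myocardial infarction. The labels put 10 libraries into 2 groups of 5. One group received phosphate-buffered saline (PBS) and the other a treatment named 4FM3. The series title concerns turning cells of the heart into another cell type in the living animal with adeno-associated virus (AAV), a gene delivery vector. The genes or vectors that 4FM3 stands for are not given in the sources used here, so no gene was treated as a known part of the treatment. Each sample also carries a time label of 8 weeks whose starting point is not stated, and a male sex label. Per the labels' protocols, hearts were perfused with cold saline, the left ventricle was kept without atria, valves or right ventricle, total RNA was depleted of ribosomal RNA, and strand-preserving libraries were made. Replicate numbers come from the labels. Nothing states outright that each library is a separate animal, so p-values measure the spread between these libraries.

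Per the submitters' processing notes the genome build was mm10. The aligner, the counting tool, the gene annotation and whether counting used the strand are not given in the sources used here. Reads from overlapping or antisense genes, from near-identical paralogs and from nuclear copies of mitochondrial genes can therefore not be separated further. The deposited table gave 3 values for each gene and library. The deposited count columns held whole-number read counts per gene. The second set, named as normalized expression in the file headers, was a signal that equalled the count times 1 factor per library, and the factors chosen by the authors ranged from 0.9311 to 1.114. The third set, deposited as transformed values per the file headers, equalled log2 of the normalized value plus 1. Only the counts entered the tests, and the other columns were used to check these relations. The table had 49585 rows. In 26 rows, holding between 0.131% and 0.161% of the counts of a library, a calendar date stood in place of a gene symbol. These rows were kept in the tests and are not named.

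Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes with few counts were removed with filterByExpr by group, which left 12906 genes, and library sizes were scaled by the trimmed mean of M-values (TMM). The quasi-likelihood test with robust dispersions compared 4FM3 with PBS, two-sided, with no covariate, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Expression per library is given as CPM, the edgeR measure of counts relative to the TMM-scaled library size. Fold changes are those of the fitted model, each with a standard error (SE). Total counts per library ranged from 6634159 to 7711177. A count of 0 allows up to 3 counts, which lies between 0.371 and 0.481 CPM in these libraries and covers counting error only.

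Gene lists for cell types, contraction, metabolism, matrix, inflammation and stress were written before the data were examined, as were the design and a first set of alternative settings. The 33 lists with at least 5 tested members were compared with all other tested genes by camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01. The test was repeated with an estimated correlation, and the limma function fry tested whether the members of a list moved, on balance, one way. A score per library, the mean log2 CPM of the members, was compared by a two-sided exact permutation test over all 252 assignments of the libraries, for which the smallest possible p is 0.00794. Members that rose or fell were counted over all genes tested and also adjusted over the list alone. Of the symbols in the lists, 32 had no row of that name in the table.

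Named genes followed a rule fixed before the data were examined. It takes the 12 genes that rose most and the 12 that fell most among those past the threshold, with a mean of at least 1 CPM and no overlap between the groups. It adds the 4 genes with the smallest p in each list described and every gene of a list of cardiac transcription factors used in reprogramming. For many lists the text gives only some of these 4 genes, so the examples shown are not the full set. Predicted genes, pseudogenes and immunoglobulin segments were counted and not named. Genes outside this rule, such as those of the circadian clock, lung, sex chromosomes and atrium singled out below the main comparison, were chosen after their values were seen. Gene positions are those of GENCODE release M21 on the same build, which held 12608 of the 12906 tested symbols (97.7%).

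The tests were checked on counts simulated from the means and library sizes of these libraries. In that simulated 4FM3 against PBS comparison of 12785 genes, 57.6% of genes changed 1.5-fold were called, 83.3% of those changed 2-fold and 100% of those changed 4-fold, and 5.42% of the calls were unchanged genes. The simulation changed 66, 66 and 64 genes at these folds, with no scaling difference between the groups. In the data 43.0% of tested genes passed and the TMM factors differed by group. These rates therefore need not hold for the real comparison. Alternatives covered DESeq2 size factors, upper-quartile factors and library size alone for scaling, other filters on low counts, the DESeq2 1.42.0 Wald test, limma-voom with quality weights, a fold threshold, a replicate block, removal of mitochondrial and ribosomal RNA genes, other list scores and leaving out each library in turn. Alternatives chosen after seeing the data left out PBS replicates 2 and 3, left out these and 4FM3 replicates 2 and 5, or thinned every library to 6634159 counts. Replicate pairs of a group differed by more than sampling noise, with a chi-square per degree of freedom between 4.537 and 18.64, so no library was a copy of another.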

Results

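The transcriptome of the left ventricle was measured in 10 libraries from infarcted mouse hearts, 5 given PBS and 5 given 4FM3, all collected 4 weeks after infarction. Total counts averaged 7433000 ± 248800 in PBS and 7075000 ± 269600 in 4FM3 (SD, n = 5 each), a difference that did not pass a two-sided exact permutation test (p = 0.0635). The data hold no uninjured hearts, so every comparison is between treated and untreated infarcted ventricles. The comparison asks how gene expression differs between infarcted ventricles of the 4FM3 and PBS groups. No group received an empty vector, so an effect of a delivery vector itself could not be told apart from one of the genes it carries.

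Ventricles of the 4FM3 group carried more RNA of mitochondrial energy metabolism, calcium handling and the sarcomere, and less RNA of collagen matrix, activated fibroblasts and TGF-beta signalling, than those of the PBS group. Of 45 nuclear genes of oxidative phosphorylation, all 45 rose, with a median log2 fold change of 0.79. Of 38 genes of fibrillar matrix and its crosslinking, 32 fell and 1 rose, with a median of -0.79. Over all genes, 5546 of the 12906 tested (43.0%) passed the edgeR quasi-likelihood test, 2700 of them higher and 2846 lower in 4FM3. Fewer of these genes had a fitted change over 2-fold, 172 higher and 522 lower, a count of estimates and not a test against 2-fold. Tested against a 1.5-fold change, 194 genes passed, 70 higher and 124 lower. The 5 values of one group lay wholly apart from the 5 of the other for 27.5% of the tested genes, against 0.794% by chance. The common biological coefficient of variation was 14.5%, and the first principal component held 52.9% of the variance and separated the groups. With library size alone as scaling, which shifted the median of all genes by -0.18 on the log2 scale, 1540 genes rose and 4967 fell, and without PBS replicates 2 and 3, an alternative chosen after seeing the data, 3521 genes passed.

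**Figure D1:**
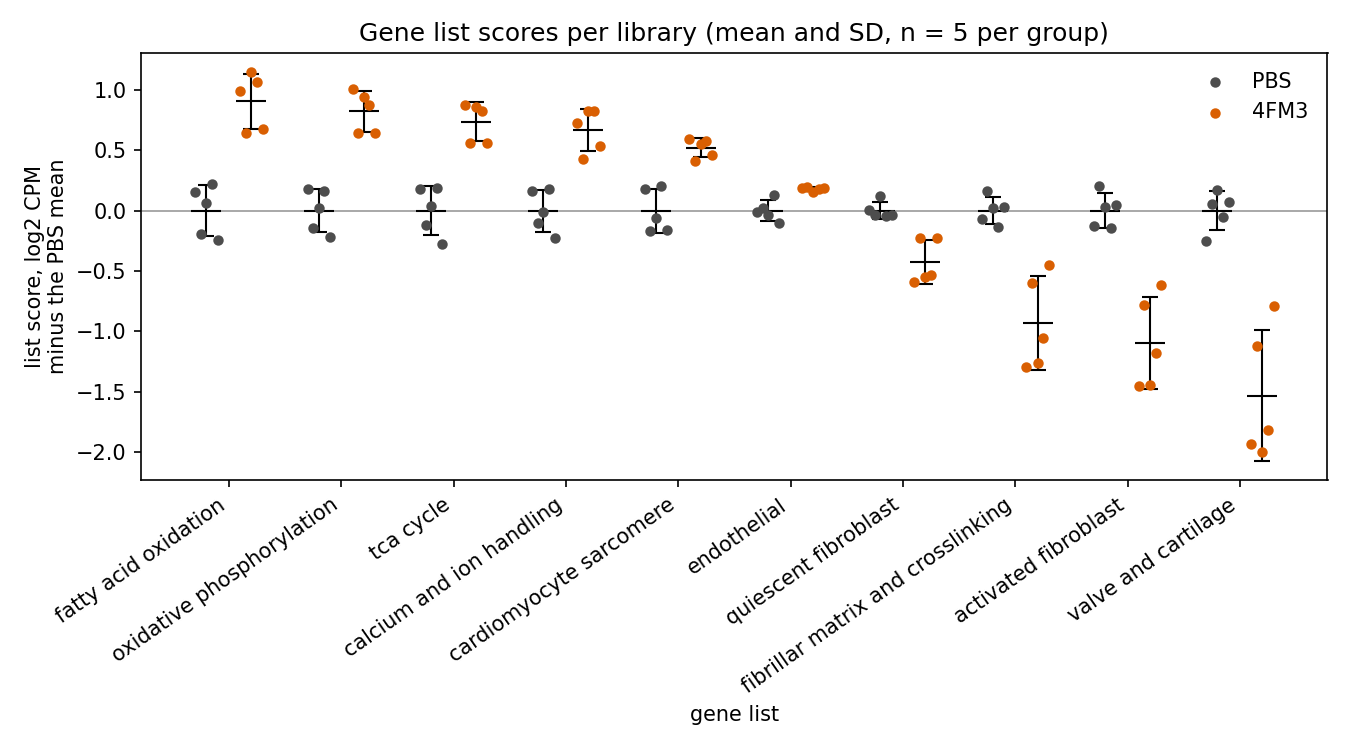
Scores of 10 gene lists per library, as the mean log2 CPM of the members minus the mean of the PBS libraries, with grey points for PBS and orange points for 4FM3 (n = 5 each) and bars for the mean and SD. The groups did not overlap for any of the 10 lists, and the difference ranged from 0.90 for fatty acid oxidation to -1.53 for valve and cartilage genes.

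Lists of oxidative phosphorylation, fatty acid oxidation, the citric acid cycle and glycolysis were called higher by camera. In the respiratory chain, Cox6a2, the muscle isoform of a subunit of cytochrome c oxidase (chromosome 7, 128205435 to 128206387), went from 52.9 ± 13.6 CPM in PBS to 203.1 ± 25.9 in 4FM3 (SD, n = 5 each), 3.84-fold higher (log2 fold change 1.94, SE 0.155, adjusted p = 0.000211). Ndufs7 and Ndufb3 of complex I rose 1.74-fold and 1.62-fold, and Cox5b 1.95-fold (adjusted p = 0.000224 for each). The oxidative phosphorylation list differed from other genes by camera (adjusted p = 3.45e-23; adjusted p = 0.313 with an estimated correlation). Of 31 genes of fatty acid oxidation 30 rose, with a median log2 fold change of 0.93 (adjusted p = 7.49e-15; adjusted p = 0.313 with an estimated correlation). They included Etfb, an electron carrier for acyl-CoA dehydrogenases (2.14-fold), Acadvl, the very long chain acyl-CoA dehydrogenase (1.96-fold), and the fatty acid transporter Cd36 (1.98-fold). All 20 genes of the citric acid cycle and pyruvate entry rose, with a median of 0.73 (adjusted p = 1.75e-11; adjusted p = 0.313 with an estimated correlation), among them Sucla2 (1.87-fold) and the pyruvate carrier subunit Mpc2 (1.82-fold). Counts adjusted over the list alone were the same for these 3 lists. Glycolysis genes moved mostly in the same direction, 15 up and 2 down of 23, also when adjusted over the list alone (adjusted p = 0.000127; adjusted p = 0.313 with an estimated correlation). Ldhb rose 1.92-fold, and the muscle enzymes Eno3 and Pgam2 rose 2.13-fold and 1.71-fold.

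Transcripts of the mitochondrial genome rose as well. All 13 tested genes were higher in 4FM3, also adjusted over the list alone, with a median log2 fold change of 0.76 (adjusted p = 6.27e-06; adjusted p = 0.313 with an estimated correlation). The most abundant of those named, mt-Co1, went from 21660 ± 3160 to 39100 ± 6560 CPM, and mt-Nd1 from 4755 ± 713 to 8897 ± 2230 CPM (SD, n = 5 each). Mitochondrial transcripts took 4.59% ± 0.529 of all counts in PBS and 7.12% ± 1.21 in 4FM3 (SD, n = 5 each; two-sided exact permutation p = 0.00794, the smallest the design allows). With PBS replicates 2 and 3 left out, 45 of 45 oxidative phosphorylation genes, 30 of 31 fatty acid oxidation genes and 20 of 20 citric acid cycle genes still rose, and 10 of the 13 mitochondrially encoded genes.

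Genes of the contracting cardiomyocyte were higher in 4FM3. Of 26 calcium and ion handling genes 23 rose and none fell, with a median log2 fold change of 0.58 (adjusted p = 4.12e-10; adjusted p = 0.313 with an estimated correlation). Ryr2, the calcium release channel of the sarcoplasmic reticulum, went from 3162 ± 313 to 5713 ± 690 CPM (SD, n = 5 each), 1.81-fold higher (SE of log2 0.112, adjusted p = 0.000271). Pln, the inhibitor of the calcium pump, rose 1.85-fold, the luminal calcium-binding protein gene Hrc 2.13-fold and the junctional protein gene Jph2 1.56-fold. Of 26 sarcomere and cardiomyocyte genes 21 rose and none fell, with a median of 0.48 (adjusted p = 6.61e-09; adjusted p = 0.313 with an estimated correlation). Cardiac troponin I, Tnni3, rose 2.10-fold, ventricular myosin light chain Myl2 went from 1843 ± 309 to 3681 ± 596 CPM, and Smyd1 and Cryab rose 1.76-fold and 1.52-fold. Adjusted over the list alone, 24 and 22 members of these 2 lists rose. With library size alone 15 sarcomere members rose and 1 fell, with a median of 0.305. A list of skeletal muscle genes had 9 of 10 tested members higher and none lower, also adjusted over the list alone (adjusted p = 0.000688; adjusted p = 0.313 with an estimated correlation). Among them, Mb and Ckm, which are also abundant in heart muscle, rose 1.77-fold and 1.81-fold, and the slow troponin gene Tnnt1 and the calcium channel gene Cacna1s, near 3 to 13 CPM, rose 2.06-fold and 1.78-fold. With no filter on low counts the skeletal muscle list was not called, and its median, then over more members near 0 counts, was -0.66.

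Cardiac transcription factors used in reprogramming were read only as expression of those genes. Of 7 tested, 4 rose and none fell, also adjusted over the list alone, and the list passed camera (adjusted p = 0.00704; adjusted p = 0.313 with an estimated correlation). The list median was 0.34, below the 0.48 of the sarcomere list, and a difference between the 2 lists was not tested. Whether any of the reads came from a delivered copy of these genes was not tested either. Hand2 went from 6.07 ± 0.787 to 9.45 ± 1.70 CPM (SD, n = 5 each; 1.56-fold, adjusted p = 0.00494), and Nkx2-5 from 35.1 ± 1.79 to 45.7 ± 3.65 CPM (1.30-fold, adjusted p = 0.00138). Gata4 and Myocd rose 1.26-fold each (adjusted p = 0.00583 and 0.00852), with overlapping groups. Tbx5 (log2 fold change 0.40, SE 0.183, adjusted p = 0.0992), Srf (0.21, SE 0.0937, adjusted p = 0.0815) and Mef2c (0.13, SE 0.0836, adjusted p = 0.212) did not pass. Tbx5 passed with the replicate number as a block (0.37) and without 4FM3 replicate 2 (0.51) and stood at 0.24 without 4FM3 replicate 4, Srf passed with limma-voom (0.24) and without 4FM3 replicate 2 (0.27), and Mef2c without 4FM3 replicate 5 (0.20). Mesp1 and Myod1 had at most 1 count in any library, too few to test. With library size alone as scaling, Gata4 and Myocd did not pass (log2 fold changes of 0.16 each), Nkx2-5, Tbx5 and Srf stood at 0.20, 0.22 and 0.04, Mef2c turned to -0.04, and 2 members of the list rose. Hand2 did not pass without PBS replicates 2 and 3 and 4FM3 replicates 2 and 5 (0.46), a combination also chosen after seeing the data, in which Mef2c and Srf stood at 0.22 and 0.37 and Srf passed.

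Matrix and fibroblast genes were lower in 4FM3. Col3a1, a fibrillar collagen gene (chromosome 1, 45311538 to 45349706), went from 3432 ± 542 to 1517 ± 409 CPM (SD, n = 5 each), 2.26-fold lower (log2 fold change -1.18, SE 0.175, adjusted p = 0.000424). Sparc, Lum and Col6a1 were 1.92-fold, 1.72-fold and 1.66-fold lower. The fibrillar matrix list passed camera (adjusted p = 1.22e-10; adjusted p = 0.355 with an estimated correlation). Of 34 genes of activated fibroblasts 28 fell and 1 rose, with a median log2 fold change of -1.01 (adjusted p = 5.56e-10; adjusted p = 0.313 with an estimated correlation). Thbs2 was 2.08-fold lower, the contractile marker Tagln 2.04-fold, Ddah1 1.82-fold and Aspn 1.81-fold. Quiescent fibroblast genes moved less, with 14 lower and 1 higher of 26 and a median of -0.41 (adjusted p = 0.000491; adjusted p = 0.393 with an estimated correlation), including Dpt (1.68-fold lower), Ccdc80 (1.79-fold lower) and Igf1 (1.56-fold lower). The score of the activated list fell by 0.67 more than that of the quiescent list on the log2 scale (two-sided exact permutation p = 0.00794, n = 5 each, chosen after seeing the data). Adjusted over the list alone, 33 matrix, 30 activated and 14 quiescent fibroblast genes fell. In all of these lists the 4FM3 libraries spread wider than the PBS libraries, with matrix scores of 7.44 and 7.58 in 4FM3 replicates 2 and 5 and between 6.74 and 6.98 in the other 3.

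TGF-beta pathway genes, a signalling route known for driving matrix production, fell in 20 of 26 cases and rose in none, also adjusted over the list alone, with a median log2 fold change of -0.61 (adjusted p = 1.53e-06; adjusted p = 0.313 with an estimated correlation). The ligand gene Tgfb3 went from 88.0 ± 5.97 to 41.2 ± 11.2 CPM (SD, n = 5 each; 2.13-fold lower), the receptor gene Tgfbr2 was 1.45-fold lower and the integrin gene Itgav 1.52-fold lower. The count was 13 of 26 when PBS replicates 2 and 3 were left out, with fewer libraries and a median of -0.63. Valve and cartilage genes, counted in tissue from which the labels say valves were removed, had 8 of 11 members lower and none higher and the lowest median of the called lists, -2.02 (adjusted p = 0.000146; adjusted p = 0.313 with an estimated correlation). The transcription factor gene Sox9 was 2.18-fold lower, Fmod 4.30-fold, Cilp2 5.12-fold and Chad 5.14-fold lower. The lowest log2 fold change of this list, -2.362 for Chad, was also the lowest of the activated fibroblast list. The valve and cartilage list is thus not separate evidence from the fibroblast genes, and the cells that made these transcripts were not tested. Adjusted over the list alone, 9 fell.

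Stress and atrial genes were mixed. Nppa, the atrial natriuretic peptide gene raised in stressed ventricles (chromosome 4, 148000722 to 148002079), went from 3370 ± 372 to 1229 ± 781 CPM (SD, n = 5 each), 2.74-fold lower (log2 fold change -1.46, SE 0.354, adjusted p = 0.0083). Its values in 4FM3 ran from 623 to 2510 CPM. The stretch-related gene Xirp2 was 1.62-fold lower. The list of fetal and stress genes as a whole was not called, with 2 members higher and 4 lower of 20 (adjusted p = 0.522), and 1 higher and 4 lower adjusted over the list alone. That list passed without PBS replicates 2 and 3 and 4FM3 replicates 2 and 5, with a median of -0.39 and 10 members lower, and Nppa then stood at -2.25. This combination was chosen after seeing the data. 4FM3 replicates 2 and 5 had the highest scores of their group for this list, 7.47 and 7.52, against 6.91 to 7.06 in the other 4FM3 libraries. They also had the highest Nppa values of their group, 1440 and 2510 CPM, against 623 to 836 CPM. The atrial list was not called, with 1 higher and 5 lower of 14, or 3 and 5 adjusted over the list alone (adjusted p = 0.997), and its median (-0.01) and mean (-0.16) had the opposite sign to the upward camera direction. The sign of the atrial median was not stable, from -0.49 to 0.40 over the alternatives. Its members Nr2f2 and Dkk3 were 1.78-fold and 2.91-fold lower and the potassium channel gene Kcnk3 1.65-fold higher.

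Macrophage, interferon response, cell cycle and immediate early lists were called lower in 4FM3 by camera, and part of their members fell. Of 38 macrophage genes 20 fell and none rose (21 adjusted over the list alone), with a median log2 fold change of -0.77 (adjusted p = 0.00046; adjusted p = 0.471 with an estimated correlation). Trem2, a receptor of scar and lipid-handling macrophages, was 1.99-fold lower, and Ccr2, the receptor of recruited monocytes, 3.35-fold lower. When PBS replicates 2 and 3, which also carried lung transcripts, were left out, 5 of 37 macrophage genes fell with a median of -0.69, and when 4FM3 replicates 2 and 5 were left out too, 3 fell with a median of -0.77 and Ccr2 did not pass (-1.89). With the replicate number as a block 10 fell and Ccr2 did not pass (-1.59), and without 4FM3 replicate 5, 13 fell. Of 35 interferon response genes 10 fell and none rose (7 adjusted over the list alone; adjusted p = 0.000244; adjusted p = 0.611 with an estimated correlation), including Ifi27 (1.46-fold lower) and Ifit3b (3.81-fold lower). The interferon median was -0.90, and genes that fell numbered 4 without PBS replicates 2 and 3 (median -0.88), 2 without those and 4FM3 replicates 2 and 5 (-0.87), and 21 with library size alone (-1.10). Without PBS replicate 5 the interferon median was -0.55. The interferon score was 4.40 and 4.80 in PBS replicates 2 and 5, between 2.89 and 3.55 in the other PBS libraries and between 2.48 and 3.54 in 4FM3. Of 31 cell cycle genes 18 fell and none rose (20 adjusted over the list alone; adjusted p = 1.25e-05; adjusted p = 0.313 with an estimated correlation). The proliferation marker Mki67 went from 31.1 ± 7.88 to 15.8 ± 1.73 CPM (SD, n = 5 each), E2f1 was 2.62-fold lower and the cyclin gene Ccnd2 1.42-fold lower. The cell cycle median was -0.64, and leaving out PBS replicates 2 and 3 gave 8 genes that fell and a median of -0.58. Immediate early genes had 8 lower and none higher of 27 (5 adjusted over the list alone; adjusted p = 0.0029; adjusted p = 0.611 with an estimated correlation), with Egr2 2.05-fold lower. The immediate early median was -0.43, and 2 genes fell without PBS replicates 2 and 3 (median -0.35) and 16 with library size alone (-0.61). By the exact permutation test the scores of the macrophage (adjusted p = 0.0624), interferon (0.109) and immediate early (0.0797) lists did not pass, and by fry the interferon (adjusted p = 0.0975) and immediate early (0.0802) lists did not pass.

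B and plasma cell genes had 4 lower and none higher of 11, also adjusted over the list alone (adjusted p = 0.0316; adjusted p = 0.426 with an estimated correlation). Sdc1, which is also made by other cell types, was 1.93-fold lower with a log2 fold change of -0.95, and -0.56 without PBS replicates 2 and 3. This list was no longer called without 4FM3 replicate 3 (median -0.51), without PBS replicates 2 and 3 and 4FM3 replicates 2 and 5 (-0.61) or with library size alone (-0.72). Lists of T and natural killer cells (1 lower of 5, adjusted p = 0.682), neutrophils (0 of 5, adjusted p = 0.937) and erythroid and platelet genes (0 of 9, adjusted p = 0.38) were not called, with the same counts adjusted over the list alone. With no filter on low counts the T and natural killer cell list was called (median -1.63).

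Endothelial and hypoxia lists were called higher in 4FM3 by camera. Of 29 endothelial genes 12 rose and 2 fell (13 and 2 adjusted over the list alone), with a median log2 fold change of 0.21 (adjusted p = 0.00672; adjusted p = 0.313 with an estimated correlation). The growth factor receptor gene Kdr rose 1.57-fold and Robo4 by 0.58 on the log2 scale, while Cd34 was 1.24-fold lower (log2 fold change -0.31). With library size alone Cd34 stood at -0.48, and 5 members rose and 5 fell with a list median of 0.04. Without PBS replicates 2 and 3 the counts were 6 and 2 with a median of 0.22. Hypoxia-responsive genes had 8 higher and none lower of 18, also adjusted over the list alone (adjusted p = 0.0316; adjusted p = 0.45 with an estimated correlation), with Egln3 2.06-fold and Vegfa 1.73-fold higher. That list was no longer called without 4FM3 replicate 5 (7 higher and 3 lower, median 0.20 against 0.26 with it), with limma-voom (0.24), with the replicate number as a block (0.25) or without PBS replicates 2 and 3 and 4FM3 replicates 2 and 5 (0.12), and 5 members rose without PBS replicates 2 and 3 (0.17). With library size alone 5 rose and 4 fell. Smooth muscle and pericyte genes went both ways, 5 higher and 9 lower of 22 (7 and 10 adjusted over the list alone; adjusted p = 0.5). The pericyte genes Abcc9 and Rgs5 were 1.69-fold and 1.36-fold higher (Rgs5 0.44 on the log2 scale, 0.27 with library size alone) and the contractile gene Cnn1 3.47-fold lower.

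The remaining lists were not called by camera. Adipocyte genes had 5 higher and 1 lower of 10, with the same counts adjusted over the list alone (adjusted p = 0.204), a median of 0.18, a mean of -0.03 and an upward camera direction. Over the alternatives the sign of the adipocyte median was not stable, from -0.50 to 0.28. The adipocyte list was called with library size alone (median 0.01), and without 4FM3 replicate 5 had 4 higher and 3 lower. Its member Thrsp, a regulator of lipid synthesis, rose 2.15-fold. Neurohumoral receptor genes had 6 higher and 2 lower of 19 (the same adjusted over the list alone; adjusted p = 0.467) with a median of 0.08, 7 and 4 without 4FM3 replicate 5 (median -0.07), and 6 and 7 with library size alone (-0.09). The neurohumoral score was 0.20 higher in 4FM3 by the exact permutation test (adjusted p = 0.0414). Lymphatic genes had 1 higher and 3 lower of 7 (1 and 4 adjusted over the list alone; adjusted p = 0.265). Schwann cell and neuronal genes had 1 higher and 2 lower of 8 (the same adjusted over the list alone; adjusted p = 0.682). Epicardial genes had 3 lower and none higher of 16 (1 adjusted over the list alone; adjusted p = 0.088), and that list passed in 6 alternatives, among them the fits without PBS replicate 3, without 4FM3 replicate 2 and without 4FM3 replicate 5 (medians of -0.88, -0.89 and -0.98). Unfolded protein response genes had 2 higher and 2 lower of 26 (2 and 1 adjusted over the list alone; adjusted p = 0.827), with a median of -0.02 and a mean of -0.03 against an upward camera direction, although the chaperone gene Hspa5 rose 1.43-fold (0.52 on the log2 scale, 0.34 with library size alone). With an estimated correlation, camera called 0 of the 33 lists in place of 11 higher and 10 lower, and 1 list had an unadjusted p under 0.05. By the exact permutation test of the scores 19 lists differed, and by fry 19 lists moved one way on balance.

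Among single genes, the largest rises by the naming rule were of Kcnv2, a voltage-gated potassium channel subunit, which went from 3 ± 1.37 to 14.6 ± 6.77 CPM (SD, n = 5 each; 4.84-fold), and Arntl, a core transcription factor of the circadian clock (chromosome 7, 113207465 to 113314126). Arntl went from 6.12 ± 1.98 to 28.1 ± 6.09 CPM (4.58-fold, log2 fold change 2.20, SE 0.219, adjusted p = 0.000211). Its partner-family gene Npas2 rose 3.67-fold. No label gives the time of day at which the hearts were collected. The channel genes Cngb3 and Aqp4 rose 4.43-fold and 4.09-fold, the ephrin gene Efnb3 3.88-fold and the acyl-CoA synthetase gene Acsm5 3.63-fold. Tmprss13, Lingo3, the adrenergic receptor gene Adra1b and the organic cation transporter gene Slc22a3 rose between 3.17-fold and 3.42-fold. Adjusted p for these 12 genes, Cox6a2 included, lay between 0.000211 and 0.00227.

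The largest fall by the naming rule was of Bmp3, a bone morphogenetic protein gene (chromosome 5, 98854415 to 98884396), from 3.56 ± 2.05 to 0.355 ± 0.236 CPM (SD, n = 5 each; 9.50-fold lower, log2 fold change -3.25, SE 0.54, adjusted p = 0.000702). The 4FM3 mean lay below the 0.424 to 0.481 CPM that 3 counts make in those libraries, so the size of the Bmp3 fall is uncertain. Without PBS replicates 2 and 3 it stood at -2.53 on the log2 scale. Angptl7 fell from 81.0 ± 35.8 to 12.9 ± 8.14 CPM (6.20-fold lower), Serinc2 was 6.28-fold lower and the collagen gene Col11a1 4.93-fold lower. H2-DMb2, of the class II antigen loading machinery, was 5.12-fold lower, with a close paralog beside it that makes its count uncertain. The receptor gene Fgfr2 and Klhl29 were 4.80-fold and 4.75-fold lower. Without PBS replicates 2 and 3 the log2 fold change of Fgfr2 was -1.72, against -2.26 with them. Napsa, an aspartic protease gene of lung epithelium, Npnt, an extracellular matrix gene, and Arfgef3 had log2 fold changes of -2.82, -2.69 and -2.67. After leaving out PBS replicates 2 and 3 these became -1.82, -0.88 and -1.65. Npnt did not pass without 4FM3 replicate 3 (-2.54) or with limma-voom (-2.36).

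**Figure D2:**
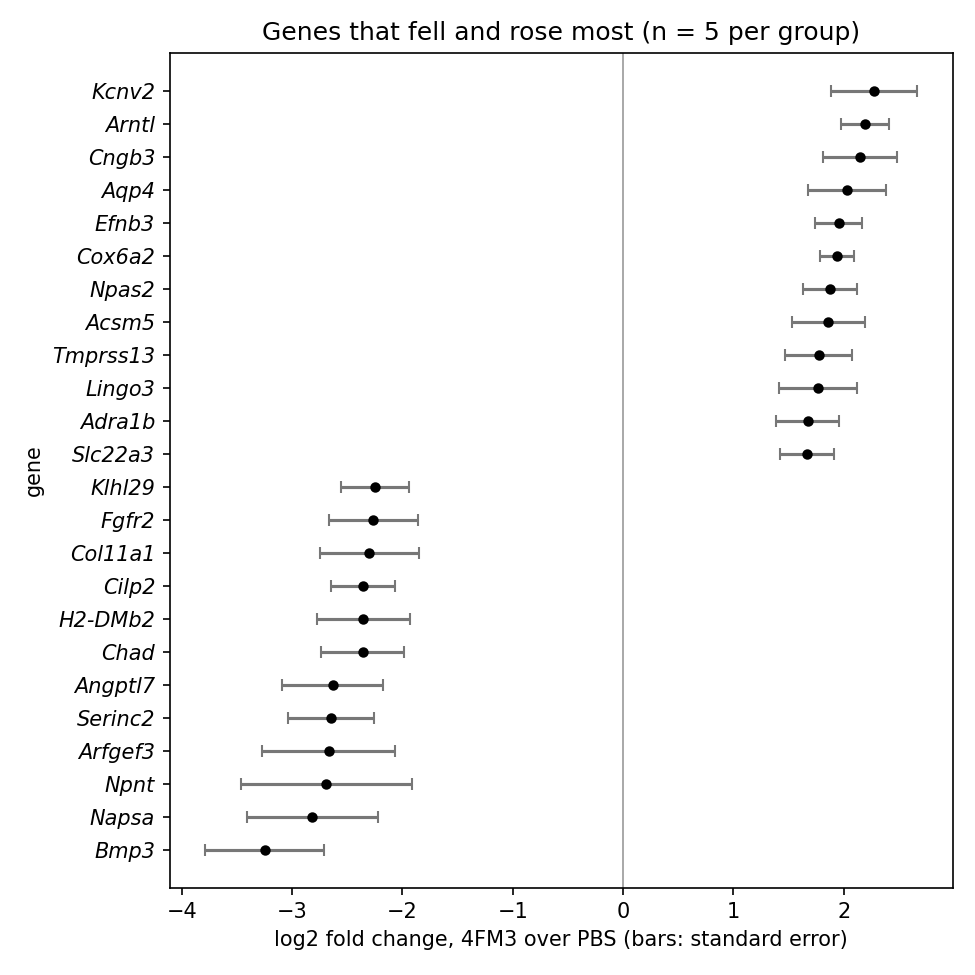
Log2 fold change of 4FM3 over PBS for the 12 genes that rose most and the 12 that fell most by the naming rule, with bars for the standard error of the fitted model (n = 5 per group). Values run from -3.25 for Bmp3 to 2.27 for Kcnv2.

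Several libraries stood apart in genes chosen after their values were seen. Sftpc, the surfactant gene of lung alveolar cells (chromosome 14, 70520949 to 70524081), had 575 CPM in PBS replicate 2, 499 CPM in PBS replicate 3 and 11.9 CPM in 4FM3 replicate 2, and 0 counts in the other 7 libraries. The library labelled 4FM3 replicate 5 had 54.3 CPM of Xist, the RNA made from the inactive X chromosome, and 0.145 CPM of the Y-linked gene Ddx3y, unlike its male label. In the other 9 libraries Xist lay at or below 0.160 CPM and Ddx3y between 84.0 and 130 CPM. The atrial myosin light chain gene Myl7 lay between 3.76 and 14.6 CPM in 4FM3, at 5.99 and 26.9 CPM in PBS replicates 1 and 5, and at or below 0.126 CPM in PBS replicates 2, 3 and 4.

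**Figure D3:**
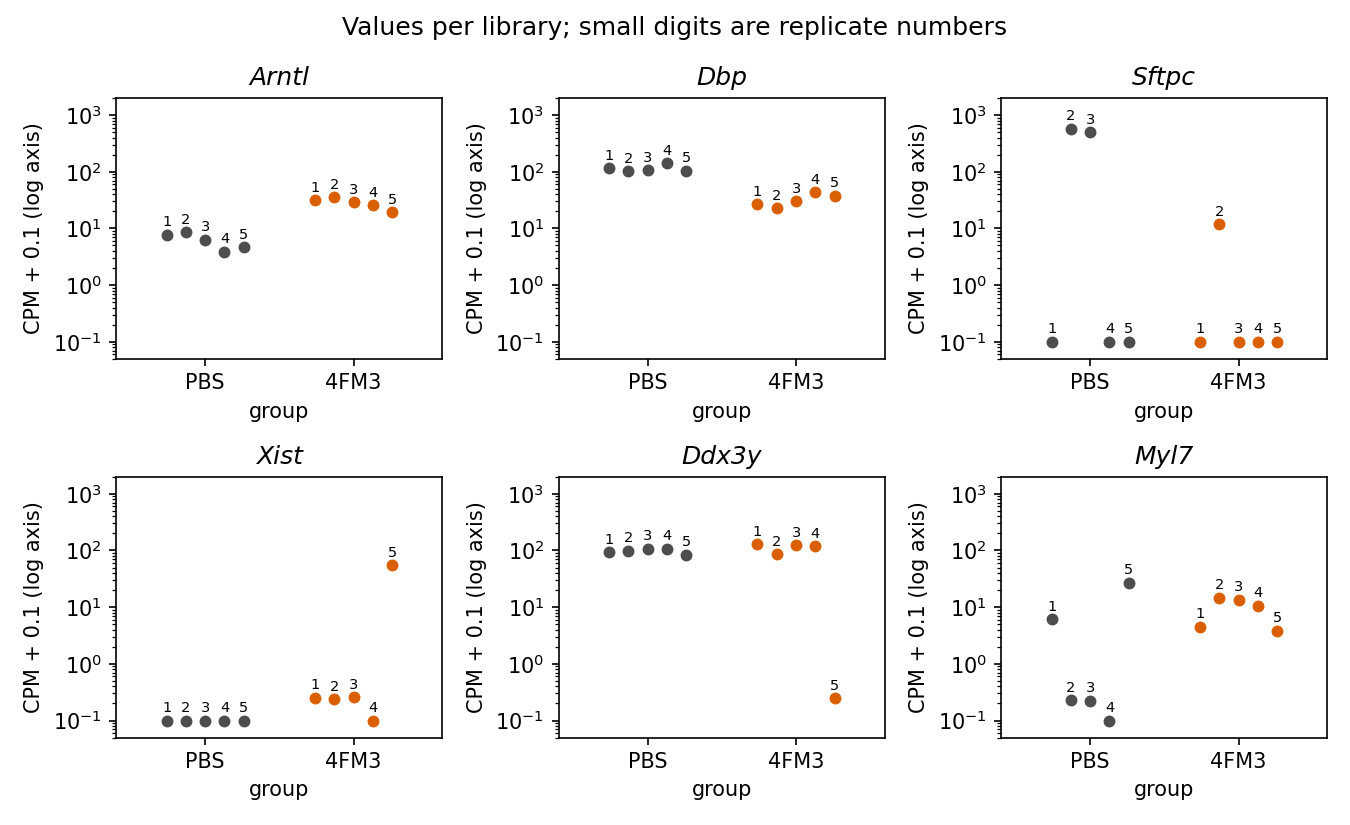
CPM per library plus 0.1, on a log axis, of 6 genes in PBS (grey) and 4FM3 (orange), with the replicate number beside each point. Arntl and Dbp separate the groups, Sftpc appears in PBS replicates 2 and 3 and 4FM3 replicate 2, Xist and Ddx3y are exchanged in 4FM3 replicate 5, and Myl7 varies within PBS.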

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

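Each library named here lay far from the others of the same group, by the gap to the nearest library over the range of the group, above 0.71 for 5 libraries. Over 284 groups of values tested in this way 15 passed, and chance gives about 14.2. Of the tests in this part, the one of the group difference without the libraries with lung transcripts was written before its result was seen, and the one of lung markers after.

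Xist in 4FM3 replicate 5 stood at 54.3 CPM against at most 0.160 CPM in the other 4 libraries of its group (ratio 0.997). In the same library Hand2 stood at 12.4 CPM against 8.13 to 9.10 (ratio 0.775), and the adipocyte score at 5.31 against 4.02 to 4.22 (ratio 0.844). In PBS replicate 2, Cilp2 stood at 26.2 CPM against 15.2 to 16.1 (ratio 0.918), and the lymphatic score at 5.42 against 5.22 to 5.28 (ratio 0.727). In PBS replicate 3, Ccdc80 stood at 510.5 CPM against 430.6 to 439.9 (ratio 0.883), and the quiescent fibroblast score at 7.04 against 6.87 to 6.92 (ratio 0.714). In PBS replicate 5, Ifit3b stood at 10.7 CPM against 3.42 to 5.03 (ratio 0.778), and Myl7 at 26.9 CPM against at most 5.99 (ratio 0.778). Cox6a2 stood at 76.9 CPM in PBS replicate 1 against 43.5 to 49.7 (ratio 0.814), below every 4FM3 library. Dbp stood at 140.7 CPM in PBS replicate 4 against 103.4 to 113.8 (ratio 0.721). Mesp1 had 1 count in PBS replicate 2 and 1 count in 4FM3 replicate 3 and 0 in the other libraries of each group (ratio 1 in both).

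Sftpc in 4FM3 replicate 2 stood at 11.9 CPM against 0 counts in the other 4 libraries of its group (ratio 1), and Napsa in that library at 1.98 CPM against 0.320 to 0.771 (ratio 0.728). The same genes were high in PBS replicates 2 and 3. A candidate source is RNA from lung tissue, and of 16 lung epithelial markers, a list drawn up after Sftpc had been seen, 11 were at least 10 times higher in both of those PBS libraries than in the mean of the other 3. The markers Hopx, Napsa, Krt7, Npnt and Epcam were not, and the first of these is also made by heart muscle. Without PBS replicates 2 and 3, the median ratio of the log2 fold changes of called genes to those with them was 0.958. The changes of the called genes as a whole thus kept most of their size without those libraries. This median takes rises and falls together, so it cannot decide how much lung RNA adds to the falls. With fewer libraries, genes that rose went from 2700 to 1853 and genes that fell from 2846 to 1668. What stays open is how much of the fall of single genes shared between lung and heart, and of immune genes that lung tissue also carries, comes from these libraries. No biological explanation was tested.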

How the results depend on the processing

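Alternatives that left out PBS replicates 2 and 3, left out those and 4FM3 replicates 2 and 5, or thinned the counts were chosen after seeing the data. Against 5546 genes called, 2700 higher and 2846 lower, leaving out 1 library in turn gave between 4573 and 5831 genes called, 2317 to 2840 higher and 2206 to 2991 lower, with 10 to 11 lists raised, 9 to 11 lowered and 17 to 22 list scores called. With library size alone 1540 genes rose and 4967 fell, so that 23.7% of the calls were rises against 48.7%. Its construction shows the cause, since the TMM factors lay between 1.026 and 1.097 in PBS and between 0.9157 and 0.9684 in 4FM3. Testing against a 1.5-fold change called 194 genes, 70 higher and 124 lower, a stricter hypothesis by construction. Without PBS replicates 2 and 3, 3521 genes were called and 1668 fell, with fewer libraries, and 62.4% of the genes called with all libraries were called again with the same sign. List scores called were then 0, and 0 again without PBS replicates 2 and 3 and 4FM3 replicates 2 and 5. In the second case the smallest exact permutation p is 0.1, above the threshold, and in the first it is 0.0179 and the cause was not tested. With an estimated correlation 0 lists were raised and 0 lowered (edgeR log2 CPM and camera), 1 list had an unadjusted p under 0.05, and fry called 19. The estimated correlation was up to 0.873 for a list, against the preset 0.01. Lists with lower estimates, such as skeletal muscle (0.12) and endothelial (0.102), lost the call too, and the cause was not tested. Over the 22 other alternatives the adjusted p of the oxidative phosphorylation list was at most 6.75e-20, of the fibrillar matrix list at most 9.9e-08 and of the skeletal muscle list at most 0.33.

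Of the named genes, 5 values reversed, none of them called with all libraries, and the cause was not tested except where stated. Mef2c went to -0.04233 with library size alone, from the shift of all genes. Leaving out 1 library, Ddx3y ranged from -0.2637 without 4FM3 replicate 1 to 0.2191 without 4FM3 replicate 5, and it stood at -0.8288 with limma-voom and at 0.3847 and past the threshold without PBS replicates 2 and 3 and 4FM3 replicates 2 and 5. The sign turned where the library without Y-linked RNA was left out, and the cause of the call was not tested. Myl7 ranged from 0.1875 without PBS replicate 4 to 2.597 without PBS replicate 5, went to -0.2085 without PBS replicates 2 and 3 and to -0.2167 when 4FM3 replicates 2 and 5 were left out too, while limma-voom gave 3.778 and a call. Over all named genes and alternatives, 2327 values kept direction and side of the threshold, 20 lost the call and 14 gained it; for lists 706 kept both, 8 lost and 9 gained the call. The remaining alternatives for the counts of calls stayed within 1.5 times. A depth of 6634159 to 7711177 counts limits calls of genes near a few CPM, and thinning to 6634159 counts called 5469 genes. The fit with the replicate number as a block called 5592 genes, 2740 higher and 2852 lower, with 94.1% of the calls kept. Deviations of libraries with the same number correlated between -0.0448 and 0.0595 and in 1 of 5 pairs was the same number the best match, so the numbers did not pair the samples. The replicate block ended the calls of the hypoxia list, Ccr2 and Cwc22 and gained those of Tbx5 and Per1.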

Other observations

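Of the tests in this part, those of chance and depth were written before their results were seen, and those of cardiomyocyte share, scar share and the clock genes, as well as the gene families below, were chosen after.

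Genes of the mitochondrial ribosome and of mitochondrial import rose along with the respiratory chain. Families were formed from the shared start of gene symbols and tested by camera, 139 families in all, of which 21 passed with the preset correlation; adjusted p was 0.571 for each family named here with an estimated correlation except where given. Of 49 tested genes of the large mitochondrial ribosomal subunit (Mrpl) 47 rose, with a median log2 fold change of 0.54 (adjusted p = 1.76e-15), and of 29 of the small subunit (Mrps) 25 rose (0.55, adjusted p = 2.61e-11). Cytosolic ribosomal protein genes were not called, with 4 higher and 4 lower of 47 Rpl genes and 3 higher and 5 lower of 40 Rps genes (adjusted p = 0.885 and 0.831; adjusted p = 0.982 and 0.969 with an estimated correlation). With library size alone as scaling, which lowers all genes, 21 Rpl and 18 Rps genes fell and 39 Mrpl and 24 Mrps genes still rose. Of the Timm genes, subunits of the inner membrane import machinery, 11 of 13 rose, as did 9 of 11 Coq genes of coenzyme Q synthesis and 10 of 15 Asb genes, adaptors of ubiquitin ligases (adjusted p = 4.71e-05, 0.00167 and 0.00546). Falling families included collagens (25 of 36 Col genes), C-type lectins (9 of 19 Clec genes), Toll-like receptors (5 of 11 Tlr genes) and annexins (6 of 10 Anxa genes), with adjusted p of 2.44e-07, 0.0313, 0.0481 and 0.0494. No family was tested again without PBS replicates 2 and 3, which carried lung transcripts. Without those libraries 5 of 37 genes of the macrophage list fell (median -0.69), against 20 of 38 with them (-0.77). Under the DESeq2, upper-quartile and library size scalings none of the families named above as rising or falling changed the sign of its median. Other called families were less stable. With library size alone the medians of Ppp, Ube and Psmd turned from 0.152, 0.153 and 0.15 to -0.0218, -0.0244 and -0.0263. The Eif median went from 0.183 to 0.00632, with 5 genes higher and 10 lower.

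Circadian clock genes moved in opposite directions by phase. Of 6 genes that peak with Arntl 5 rose (median log2 fold change 1.22), and of 10 that peak with Dbp 9 fell (median -1.14), while Per1 was at -1.40 (adjusted p = 0.0596) and passed in 7 of 23 settings, such as the replicate block (-1.66) and without 4FM3 replicate 5 (-2.04). Dbp went from 113.8 ± 15.6 to 32.2 ± 8.36 CPM (SD, n = 5 each) and Per3 from 39.9 ± 7.51 to 10.8 ± 2.06 CPM. A shift of cell composition stays open: the difference between the scores separated the groups (two-sided exact permutation p = 0.00794, n = 5 each), but these genes were picked after they had been seen to move apart, and cell types can differ in clock gene levels. Hearts collected at different times of day, and an effect of the treatment or of the state of the heart on the clock, cannot be told apart: the score difference rose by 2.42 on the log2 scale, from -2.67 ± 0.336 in PBS to -0.255 ± 0.473 in 4FM3, which either predicts, and no label gives the time of collection. The groups did not overlap, with 4FM3 libraries between -0.944 and 0.211 and PBS libraries between -3.145 and -2.31.

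The breadth of the difference between 4FM3 and PBS was set against chance, depth and tissue composition. A difference in time of day at collection, left open for the clock genes, was not tested for the other genes. If present, it would coincide with the groups, so it cannot be told apart from the treatment for any gene. Among 100 of the 126 splits of the libraries into 5 and 5, only 1, the real one, called as many genes, and the highest of the others called 5 genes, which argues against chance. After thinning to equal totals 95.5% of the called genes were called again with the same sign, which argues against depth. A larger share of cardiomyocyte RNA alone predicts that the oxidative score rises no more than the sarcomere score. The oxidative score rose by 0.302 more on the log2 scale (two-sided exact permutation p = 0.00794, n = 5 each). This does not settle the question, because the outcome depends on the reference list, chosen after seeing the data. Sarcomere members ran from -0.149 to 1.073. The calcium and ion handling score rose by 0.669 against 0.821 for the oxidative score, a gap that was not tested. For the matrix genes, a smaller share of scar in the tissue sampled and lower expression within fibroblasts cannot be told apart: activated genes fell by 0.67 more than quiescent ones (change -0.67), which both predict. A higher share of surviving muscle may thus account for part of the pattern, and an effect of the treatment stays open as a hypothesis.

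Cwc22 lay between 17.7 and 429 CPM in PBS and between 12 and 42.1 CPM in 4FM3, and Lars2 between 33.8 and 42.5 CPM in PBS and between 46.5 and 207 CPM in 4FM3, both chosen after their values were seen. Cwc22 had a log2 fold change of -2.63 (adjusted p = 0.0428) and kept its call in 12 of 23 settings. It stood at -1.74 without PBS replicate 5 and at -1.72 with limma-voom, not called in either. Lars2 had one of 1.45 (adjusted p = 0.0161), not called when PBS replicates 2 and 3 were left out (1.40) or when 4FM3 replicates 2 and 5 were left out too (1.12).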
